A study of Mus musculus with 16 samples.

How the data were processed

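Total RNA of the right kidney of 4 Pept2 knockout males and 1 pool of RNA from 5 wild-type right kidneys were compared on two-colour spotted cDNA arrays. Per the labels, RNA was reverse transcribed and labelled indirectly with Cy3 or Cy5, and the slides were scanned on a GenePix 4000A and quantified in GenePix Pro 3.0. Per the labels, the authors subtracted background from mean intensities and scaled them so that the median ratio of an array became 1. The deposited values are log2 ratios of the channels of each array, 1 value per probe and array, and which channel is the numerator is not given in the sources used here. The labels give the RNA of each channel but not which dye it carried. The base of the logarithm was worked out from the values: of the distances between the 10 most repeated values of each array, 45.0% matched log2 of a fraction of whole numbers up to 20 within 2e-06, against 0.1% for natural and 0.0% for decimal logarithms. Every deposited value (100.0% of 222948) ended in the digit 3, for which no reason is given in the sources used here. Blank cells were left blank. The filter behind them is not given in the sources used here, and without intensities no filter on dim spots could be set. The deposited medians of the arrays lay between -0.093 (array 3 of mouse 4) and 0.008.

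The direction of the ratios was examined before any average. Arrays of one mouse in the same orientation correlated at a median r of 0.25 across probes (8 pairs), and arrays of one mouse in opposite orientation at -0.11, with 15 of 16 pairs negative. Arrays of different mice correlated at a median of 0.17 in the same orientation and -0.04 in opposite orientation. The highest r was 0.62, between array 3 of mouse 3 and array 1 of mouse 4, above the highest within a mouse (0.53), and the F test between mice, which takes arrays as independent, does not allow for this. Probes are not independent replicates in these correlations, and a dye bias would give the same signs, so they do not decide whether the values had been turned to one direction. The sign of Slc15a2, which followed the channel of the knockout RNA on all 16 arrays, was used for that. The design written beforehand took the value as channel 2 over channel 1, under which the targeted gene would be higher in knockout kidney. The values were instead read as channel 1 over channel 2, the likely direction, and the sign was turned on the arrays with knockout RNA in channel 2. Both readings give the same counts and p-values with the directions exchanged.

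Each array was centred on its median. A mouse's value was the mean of its orientation means, so arrays counted as technical replicates and n was 4 mice. A probe was tested if each mouse had a value in each orientation (10804 probes), and a gene was the mean of the probes that name it alone (6191 genes, 833 of them with more than 1 probe). Of 20205 probes, 11723 had 1 gene symbol, 806 several and 7676 none, and 11590 of those with 1 symbol were matched by gene identifier to the current gene table (assembly GRCm38.p6), which changed no symbol. That table was used for names and gene order only. The ratio against 0 was tested two-sided with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences between mice were tested at array level by a moderated F test with a dye term, using the variance moderation of limma, and a dye effect as the orientation difference of each mouse. Array replicates measure technical spread, so the F test compares these 4 animals and not genotypes.

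The 16 gene lists and 10 marker lists were fixed beforehand, and 24 with at least 5 measured genes were tested with limma's camera at its preset correlation, with an estimated correlation and fry as alternatives. Genes were named by a rule also fixed beforehand. It takes Slc15a2, up to 12 genes per direction past the threshold with the same sign in all mice and both orientations, up to 4 members of each list with the smallest p, and the 20 genes with the largest standard deviation between mice among those past the F test. Other genes were named after their values were seen: the members of the lists over-represented among differing genes, Mark3 and Txnip. The enrichment of lists among differing genes (Fisher's exact test over 24 lists, with the 6191 tested genes as background) and its repeat with each mouse left out were also chosen after the data were examined.

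The probe tests against wild type, between mice and between dye orientations were tested on simulated data with the real pattern of blanks. The list test was tested on simulated values per mouse, without blanks and without correlation between genes. For the comparison with wild type, 88 of 100 probes changed by 0.5 on the log2 scale and 99 of 100 changed by 1 were called, with 7 calls among 10604 unchanged probes. The simulation held no error of the wild-type pool that all arrays share, so the 7 calls leave out false calls from that source. For differences between mice, 134 of 200 probes with a simulated spread of 0.5 were called, and for the dye effect 183 of 200. A list shifted by -0.15 was called and none of 29 unshifted lists was. In the real ribosomal list the estimated correlation between genes was 0.405, so this does not give the rate of false calls for correlated lists. The alternatives fixed beforehand were no recentring, equal scale of arrays, quantile normalization, other filters on blanks, the median of arrays, a random block for the mouse, single orientations, arrays 1 and 2 or 3 and 4 alone, robust moderation, 1 probe per gene and each mouse left out. The opposite reading of the ratio, the arrays without array 3 of mouse 4, the probes that share 1 profile and the lists without Slc15a2 (camera and fry) were added after the data were seen. Figures and permutation tests used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.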

Results

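Kidney transcripts of 4 male mice lacking Slc15a2 (the Pept2 knockout) were measured on spotted cDNA microarrays against 1 RNA pool of 5 wild-type kidneys. Slc15a2 encodes PEPT2, the proton-coupled transporter through which the proximal tubule takes up dipeptides, tripeptides and peptide-like drugs from the filtrate. The animals were 88 (±2) days old and came from matings within a line of mixed C57BL/6 and 129Sv background, and right kidneys were used throughout. Each knockout mouse was hybridised on 4 arrays, and the knockout RNA was in channel 1 on 2 of them and in channel 2 on the other two, so that 16 arrays stood for 4 independent animals. Of 20205 probes, between 10134 (50.2%) and 18400 (91.1%) carried a value on an array, and 3966 carried one on all 16 arrays. The number of mice and arrays limits the precision of each ratio. The median standard error of a gene's log2 ratio was 0.052 over 4 mice. The wild-type RNA was never hybridised by single animal, so every test against 0 leaves out the spread between wild-type kidneys, and an error of the pool would be shared by all 4 mice.

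The first comparison asked whether the targeted gene itself was altered in each animal. Slc15a2 differed from the wild-type pool on all 16 arrays, by far more than the spread between mice: the mean log2 ratio was -2.51 (SE 0.10, n = 4 mice), which is 5.71-fold lower in knockout kidney, at an adjusted p of 2.17e-05 in limma. The ratios of the mice were -2.17, -2.74, -2.81 and -2.33. The labels do not state which channel is the numerator of the deposited ratio. As deposited, Slc15a2 was positive on all 8 arrays with knockout RNA in channel 2 and negative on all 8 arrays with knockout RNA in channel 1. The values were therefore read as channel 1 over channel 2, the likely direction, whose basis is that a gene targeted in a knockout is expected to lose transcript. Under the opposite reading, the one written down beforehand, Slc15a2 would be at a log2 ratio of 2.51 and every "higher" and "lower" of knockout against wild type given here would be exchanged. Slc15a2 had 1 probe, whose place relative to the deleted part of the gene is not given in the sources used here, and because it set the direction it is no independent evidence of it.

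**Figure D1:**
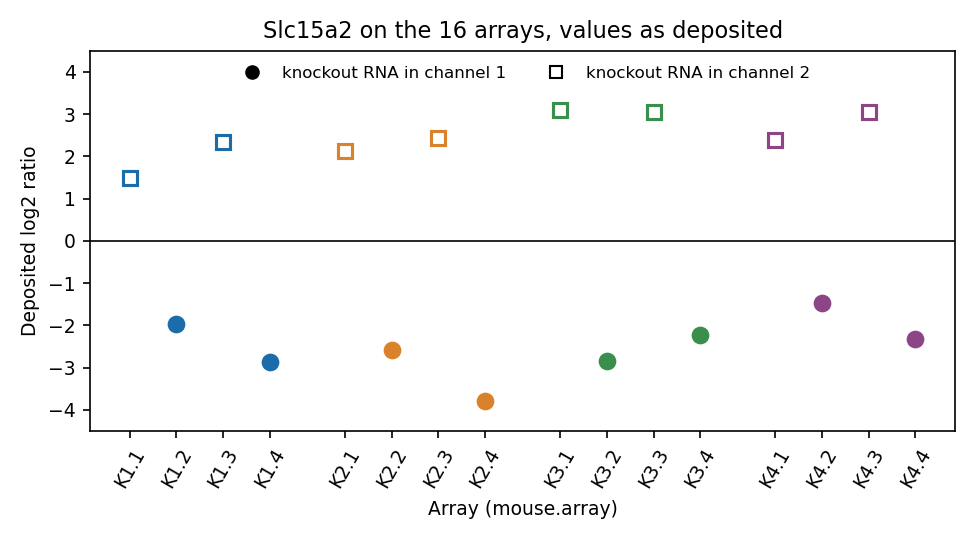
Deposited log2 ratio of Slc15a2 (vertical axis) on each of the 16 arrays (horizontal axis, mouse and array number, coloured by mouse); filled circles have knockout RNA in channel 1 and open squares in channel 2. All 8 squares lie above 0, between 1.49 and 3.09, and all 8 circles lie below 0, between -1.47 and -3.78.

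Beyond the targeted gene, 12 genes in knockout kidney differed from the wild-type pool past the adjusted threshold. Transcripts of Rdh16f2, a retinol dehydrogenase family member, were higher in knockout kidney at a log2 ratio of 0.66 (SE 0.07, 1.57-fold), and so were those of Slc22a8, the organic anion transporter of the basolateral tubule membrane, at 0.48 (SE 0.05, 1.4-fold). Also higher were Tst, a mitochondrial sulfurtransferase, at 0.45 (SE 0.05), and Slc7a7, a light chain of the basolateral exporter of cationic amino acids, at 0.37 (SE 0.05). Among the genes that were lower, Eaf2, a cofactor of transcription elongation, lies next to Slc15a2 in gene order and stood at -0.59 (SE 0.06, 1.51-fold lower). The nuclear long noncoding RNA Malat1 stood at -0.56 (SE 0.05, 1.48-fold lower) with an adjusted p of 0.00313, second to Slc15a2.

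The other genes past the threshold were all lower in knockout kidney. Hsd11b1, which regenerates active glucocorticoid, was lower at -0.56 (SE 0.06), Odc1, the first enzyme of polyamine synthesis, at -0.55 (SE 0.07), Idi1 of the isoprenoid pathway at -0.51 (SE 0.07), and Hsd17b11, a lipid droplet dehydrogenase, at -0.43 (SE 0.05). The organic anion transporter Slco1a6 was lower at -0.39 (SE 0.05). Slc35a5, a member of the nucleotide sugar transporter family and 56 places from Slc15a2 in gene order, was lower at -0.35 (SE 0.05), with its 2 probes apart in size. One probe stood at -0.52 and passed at probe level (adjusted p = 0.0334), while the gene taken from the other probe stood at -0.18 with an adjusted p of 0.18, and the gene did not pass when any 1 mouse was left out. Every one of these genes had the same sign in all 4 mice and in both dye orientations. The naming rule required this, so it is no separate evidence for the calls.

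In limma, 13 of 6191 genes passed an adjusted p of 0.05, 4 higher and 9 lower, and 22 were at an adjusted p under 0.1. At an unadjusted p under 0.05 there were 1041 genes, more than a share of 0.05. That share is the chance rate only without an error of the shared pool, so the excess need not reflect the knockout. At probe level 10 of 10804 passed, 5 in each direction. They included 1 probe annotated to 2 genes, which is left unnamed and which stood at 2.36 (SE 0.14, 5.14-fold higher, from 1.89 to 2.9 in the 4 mice), and 1 probe without a gene name at 0.41. Without mouse 2 Slc15a2 alone remained past the threshold, without mouse 1, 3 or 4 there were 3, 6 and 5 genes, and there was 1 gene on the arrays with knockout RNA in channel 2, against 10 genes, 7 of them among the 13, with knockout RNA in channel 1. No gene other than Slc15a2 therefore passed in all of these subsets. Treating the arrays as 16 measurements with the mouse as a random block raised the count to 401 genes, 140 higher and 261 lower, among them all 13. The correlation within mouse was put at 0.053 in that fit, so technical arrays counted nearly as independent animals. Its count is therefore no evidence of more changed genes.

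**Figure D2:**
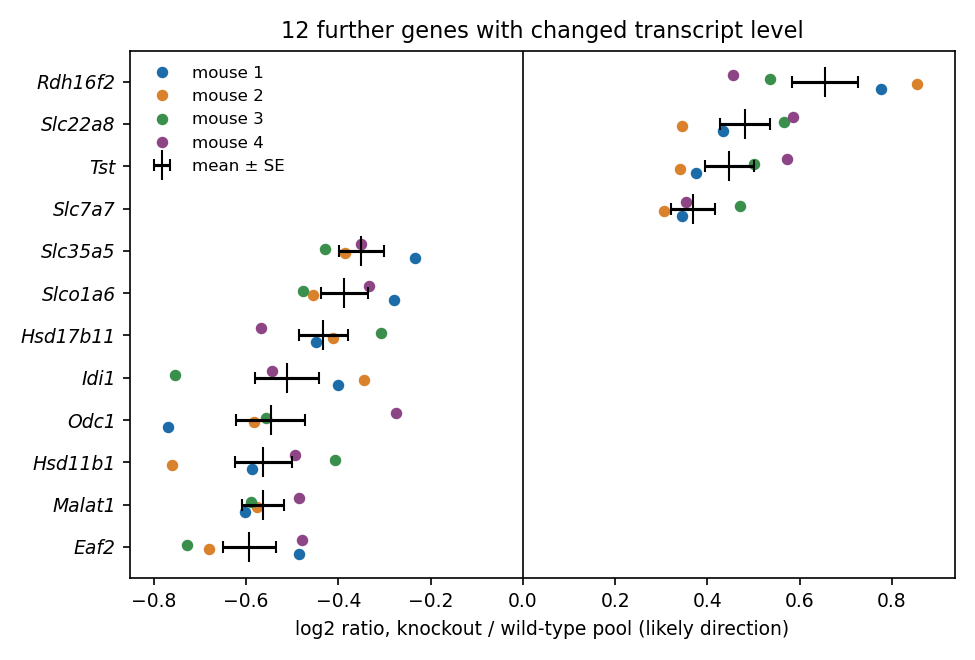
Log2 ratio of knockout mouse over wild-type pool (horizontal axis, likely direction) for the 12 genes other than Slc15a2 that passed an adjusted p of 0.05; coloured points are the 4 mice and black bars the mean ± SE. The 4 mice lie on one side of 0 for each gene, above it for Rdh16f2, Slc22a8, Tst and Slc7a7 and below it for the rest.

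The next comparison was of gene groups fixed before the data were examined. Among peptide transporters and peptidases, which handle the same substrates as PEPT2, 14 of 16 measured genes had a negative ratio and the list was lower as a whole (median log2 ratio -0.09, camera adjusted p = 0.00322, and 0.0456 without Slc15a2). With an estimated correlation between genes the adjusted p was 0.408. With knockout RNA in channel 1 alone the median was -0.07 (camera adjusted p = 0.252), and in channel 2 alone -0.17 (0.000315). On arrays 1 and 2 the median was -0.04 (0.144), and on arrays 3 and 4 it was -0.115 (0.00641). Without mouse 2 the median was -0.05 (adjusted p = 0.0322). Slc15a2 was the 1 member past the threshold over all genes. Adjusted over the list alone, 4 members were lower and 1 was higher. The dipeptidase Cndp2 stood at -0.27, the brush border protease Mep1b at -0.27 and Ace at -0.25. Androgen-responsive kidney genes were also lower: all 8 measured members had a negative ratio, with a median of -0.17 (camera adjusted p = 7.62e-05, and adjusted p = 0.408 with an estimated correlation). Hsd11b1 and Odc1 were past the threshold over all genes, and 5 members were lower adjusted over the list alone, among them the alcohol dehydrogenase Adh1 at -0.27. Cyp4b1 stood at -0.15.

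Ribosomal protein genes had a negative ratio in 41 of 45 measured members (median -0.13, camera adjusted p = 5.89e-10), and genes of oxidative phosphorylation in 59 of 69 (median -0.09, adjusted p = 1.79e-07). With an estimated correlation the adjusted p was 0.551 for ribosomal proteins and 0.63 for oxidative phosphorylation. No single member of either list passed over all genes, while 19 ribosomal and 8 respiratory genes were lower adjusted over the list alone. Rpl39 at -0.30, Rps27l at -0.24, Cox7b at -0.30 and Uqcrb at -0.27 had the smallest p. By mouse, the ribosomal median was -0.22, -0.03, -0.10 and -0.20, and that of oxidative phosphorylation was -0.10, 0.01, -0.13 and -0.19, so that mouse 2 lay closest to 0 for both lists and above it for oxidative phosphorylation. The size differed between arrays of the same mice. The ribosomal median was -0.21 on arrays 1 and 2 against -0.06 on arrays 3 and 4, and that of oxidative phosphorylation -0.16 against -0.04, and on arrays 3 and 4 neither list passed (adjusted p = 0.0966 and 0.173). Immediate early and stress genes were lower as a list (20 of 28 negative, median -0.05, adjusted p = 0.0412, and adjusted p = 0.699 with an estimated correlation), with no member past the threshold over all genes and 3 lower adjusted over the list alone. The endoplasmic reticulum chaperones Hsp90b1 and Hspa5 stood at -0.30 and -0.26. By mouse, the median was 0.02, -0.08, -0.18 and -0.14. Without mouse 1 it was -0.13 (adjusted p = 0.000541), and on arrays 1 and 2 it was -0.14 (0.00866). Without mouse 2 or mouse 3 this list did not pass (medians -0.06 and -0.03, adjusted p = 0.13 and 0.222). Nor did it pass with knockout RNA in channel 1 alone (median -0.06, adjusted p = 0.0687) or in channel 2 alone (-0.07, 0.144), on arrays 3 and 4 (-0.13, 0.111), or for probes with a value on all arrays (-0.14, 0.0887).

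None of these 5 lists passed camera with an estimated correlation. The rotation test fry, which asks whether a list's genes move one way on balance, passed for the peptide list (adjusted p = 0.0117, and 0.0327 without Slc15a2) and the androgen list (0.0474) only. Fry's mixed test, which asks whether genes of a list change in either direction and does not compare the list with other genes, passed for 10 of 24 lists. These were the peptide list with Slc15a2 included (adjusted p = 0.00199), fatty acid oxidation (0.00199), organic ion transporters (0.00797), proximal tubule markers (0.00974) and amino acid transporters (0.0114). The others were the androgen list (0.0114), amino acid metabolism (0.0164), and glutathione metabolism, circadian genes and the neighbours of Slc15a2 (0.0216 each). Over all genes, 1041 of 6191 were at an unadjusted p under 0.05 in limma, and some lists share members, so these passes are not particular to the lists.

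The other functional lists did not pass camera. Of 16 amino acid transporters 11 had a positive ratio (median 0.06, adjusted p = 0.0766). Slc7a7 was higher, its heavy chain partner Slc3a2 stood at 0.12 and Slc7a8 at -0.24. Adjusted over the list alone, 2 members were higher and 1 was lower. Organic ion and drug transporters went both ways (adjusted p = 0.781), with Slc22a8 higher, Slco1a6 lower and Slc13a3 at 0.21, and with 2 higher and 1 lower adjusted over the list alone. Of the 32 genes of amino acid metabolism (adjusted p = 0.116), Odc1 passed over all genes, and adjusted over the list alone 1 was higher and 2 were lower. Sardh stood at -0.36 and Hpd at 0.27. In glutathione metabolism (24 genes, adjusted p = 0.538), Gclc, the catalytic subunit of the rate-limiting ligase, stood at -0.30 and was the 1 member past the threshold adjusted over the list alone, and Gstm1 stood at 0.24. In fatty acid oxidation (31 genes, adjusted p = 0.652), 3 members were higher and 2 lower adjusted over the list alone, with Acot3 at 0.26 and Acox2 at -0.39.

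Of 10 genes of cholesterol and sterol synthesis (adjusted p = 0.387), Idi1 was lower, and 3 were lower adjusted over the list alone, with Hmgcs1 at -0.21. Among 9 circadian clock genes (adjusted p = 0.552), 3 were higher and 1 was lower adjusted over the list alone, with Hlf at 0.29, Cry1 at 0.18 and Nfil3 at -0.19. The kidney injury list (16 genes, adjusted p = 0.638) had 1 member lower adjusted over the list alone, and Col3a1 stood at -0.32. The antigen presentation and interferon list (20 genes, adjusted p = 0.908) had none, with Ifit3 at -0.16. The renin-angiotensin list (8 genes, adjusted p = 0.905) had 1 lower, with Kng1 at -0.19. Of 21 genes neighbouring Slc15a2 on its chromosome, 15 had a negative ratio (median -0.06, adjusted p = 0.0505), Eaf2 passed over all genes and 4 were lower adjusted over the list alone. Cox17 and Mylk, 19 and 30 places away, stood at -0.26 and -0.29.

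Markers of kidney cell types and of attached tissue did not pass camera. Collecting duct markers had a positive ratio in 10 of 12 genes (adjusted p = 0.116), with Aqp2, the vasopressin-regulated water channel, at 0.27 and past the threshold adjusted over the list alone. Of 12 proximal tubule markers (adjusted p = 0.308), Slc22a8 was higher, and adjusted over the list alone 3 were higher and 1 was lower, with Miox at 0.16. Endothelial markers had a negative ratio in 7 of 8 genes (adjusted p = 0.0673, 2 lower adjusted over the list alone), with Ehd3 at -0.17 and Esam at -0.19. Smooth muscle and fibroblast markers had a negative ratio in 8 of 11 (adjusted p = 0.0916, 2 lower adjusted over the list alone), with Fbln1 at -0.18. Loop of Henle and distal tubule markers (5 genes, adjusted p = 0.652, 1 lower adjusted over the list alone, Ppp1r1a at -0.20), leukocyte markers (11 genes, 0.908, none), adipose markers (5 genes, 0.769, 1 lower, Lpl at -0.23) and adrenal markers (5 genes, 0.652, none) did not pass. With 2 erythroid and 4 podocyte markers measured, these lists were too short to be tested. Their medians were 0.05 and -0.05. The median and the camera direction differed in sign for the circadian, fatty acid oxidation, organic ion, antigen presentation, leukocyte and renin-angiotensin lists.

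**Figure D3:**
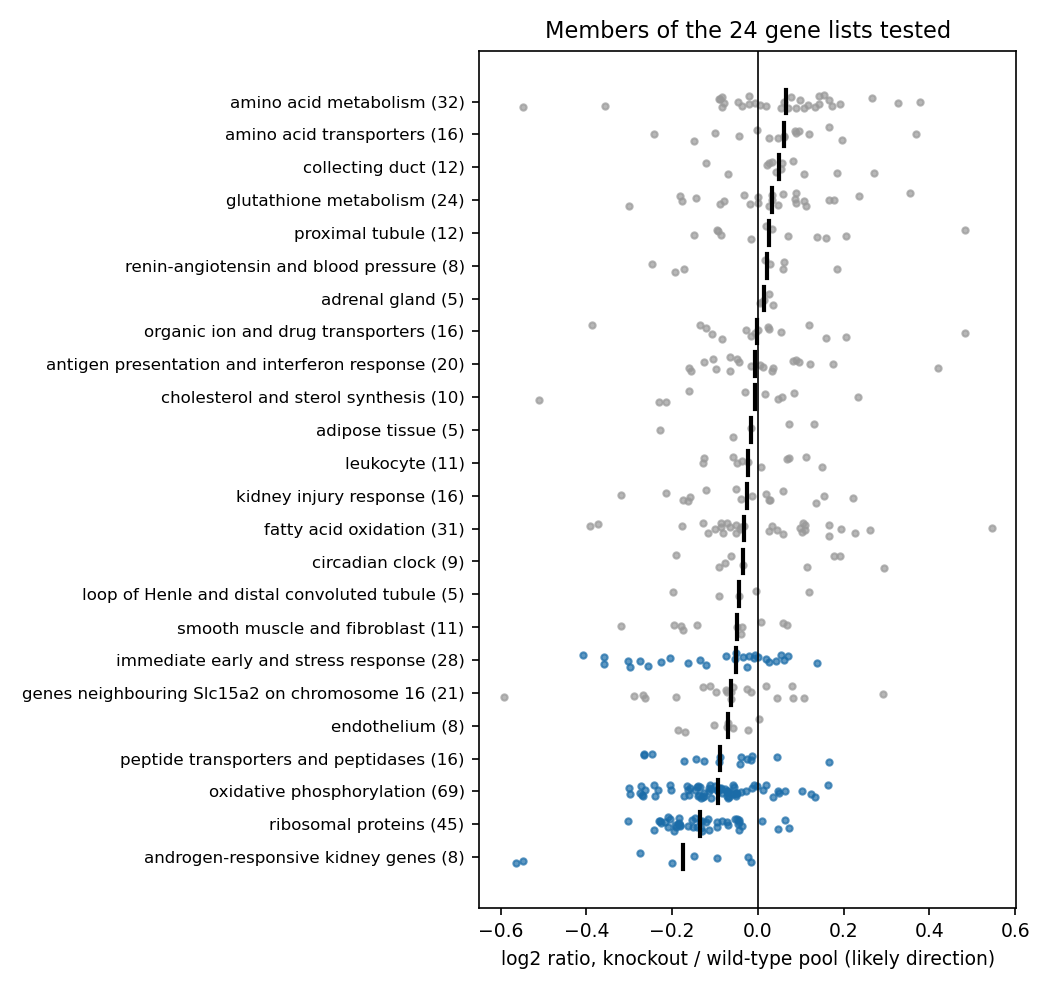
Log2 ratio of knockout over wild-type pool (horizontal axis, likely direction) of each measured member of the 24 lists tested, with the number of members in brackets; each point is 1 gene, black ticks are list medians, and blue marks the 5 lists that passed camera with its preset correlation. Slc15a2 at -2.51 is left out of the points but not of the medians, and the blue lists have medians from -0.17 to -0.05.

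Another comparison asked how far the kidneys of single knockout mice differed from each other, in which the shared pool cancels. The widest spread was that of Svs5, a secretory protein of the seminal vesicle, which stood at 4.94 in mouse 3, 1.09 in mouse 4, 0.21 in mouse 1 and -0.09 in mouse 2. Cyp4a14, a fatty acid hydroxylase, stood at 1.56 and 0.95 in mice 1 and 2 against -0.34 and 0.01 in mice 3 and 4. The aldehyde dehydrogenases Aldh1a7 and Aldh1a1, close paralogs that a spotted cDNA need not tell apart, were highest in mouse 2 (0.94 and 0.80). Serpina1b, an antitrypsin gene, stood at -1.58 in mouse 3 and between -0.31 and -0.04 in the other mice. Pttg1, which encodes securin, stood at -1.34 in mouse 2 alone, and the kinase gene Alpk3 at 1.31 in mouse 1 alone. The cold-inducible Cirbp was highest in mouse 3 (1.18) and in mouse 4 (0.60). Dnase1 and Azgp1 were above the pool in mice 3 and 4 and below it in mice 1 and 2, with values in mouse 3 of 0.82 and 0.52. 1810037I17Rik ranged from -0.79 in mouse 1 to 0.87 in mouse 4.

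Another 7 of the 20 genes with the widest spread, Ucma, Rlf, Tap1, Cdca8, Il6st, Gamt and Rhob, were measured by probes that share 1 profile with 19 further probes, with medians of -0.45, 0.27, 1.07 and 0.65 over the 26 probes in mice 1 to 4. Another probe of Rlf with values on 14 arrays had an r of 0.18 with that profile. Cap1 stood at 1.07 in mouse 3 and Nup155 at 0.72. The moderated F test over mice, with arrays as technical replicates, passed for 161 of 6191 genes and for 252 of 10804 probes, and for 210 probes when the shared-profile probes were left out, an alternative added after the data were seen. The count was 96 probes without mouse 1, 118 without mouse 2 and 81 without mouse 3. The shared-profile set holds only probes with r above 0.9 to 1 central probe, so probes that follow the profile less closely were kept. Nup155 and Cirbp, also lowest in mouse 1 and highest in mouse 3, still passed the F test without that set (adjusted p = 0.00014 and 0.00447). The 210 probes need not be separate differences between mice. Several genes did not pass with 1 mouse left out, which also lowers the power, so not each of these calls rested on that mouse. The SD was 0.06 for Pttg1 without mouse 2 but still 0.40 for Tap1 without mouse 1. Without mouse 3 the adjusted p was 0.167 for Svs5 (SD 0.61 among the other mice), 0.428 for Serpina1b and 0.311 for Cirbp. It was 0.864 for Pttg1 and 0.167 for Aldh1a1 without mouse 2, and without mouse 1 it was 0.841 for Alpk3, 0.117 for Nup155, and 0.144, 0.0865 and 0.0604 for Rlf, Cdca8 and Tap1 of the shared profile. Cirbp also did not pass with arrays brought to equal scale (adjusted p = 0.108) or with quantile normalization (0.116).

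Among the fixed lists, stress genes were over-represented among the differing genes, with 7 of 28 (Fisher's exact test, two-sided, adjusted p = 0.000127). The inducible heat shock gene Hspa1a stood at 0.34 in mouse 1 and at -0.51, -0.89 and -0.38 in mice 2, 3 and 4. Its cochaperone Dnajb1 stood at 0.38, -0.23, -0.74 and -0.32. The others were Ccn2, Gadd45g, Hspa8, Hsph1 and Klf2. Fatty acid oxidation genes were next, with 5 of 31 (adjusted p = 0.0132). These were Cyp4a14, Acox2, Ech1, Acad9 and Plin2, a lipid droplet coat protein that stood at 0.28 in mouse 2 and at -0.34, -0.74 and -0.70 in mice 1, 3 and 4. The kidney injury list (3 of 16, Col1a1, Krt18 and Timp1) and the adipose markers (2 of 5, Car3 and Fabp4) each gave an adjusted p of 0.0452. Fabp4 stood at 0.34 in mouse 2 and -0.47 in mouse 4, and Car3 at 0.60 in mouse 3. None of the other 20 lists tested passed. Fisher's test takes genes as independent, while the estimated correlation between genes was 0.16 in the stress list and 0.252 in fatty acid oxidation. Without mouse 1 none of the 28 stress genes was among the differing genes, and fatty acid oxidation did not pass without mouse 2 or mouse 4 (adjusted p = 0.0543 and 0.134). With 1 mouse left out, the kidney injury list passed only without mouse 4 (0.0391) and the adipose markers only without mouse 1 (0.00991), and without mouse 4 the smooth muscle and fibroblast markers also passed (0.0188).

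**Figure D4:**
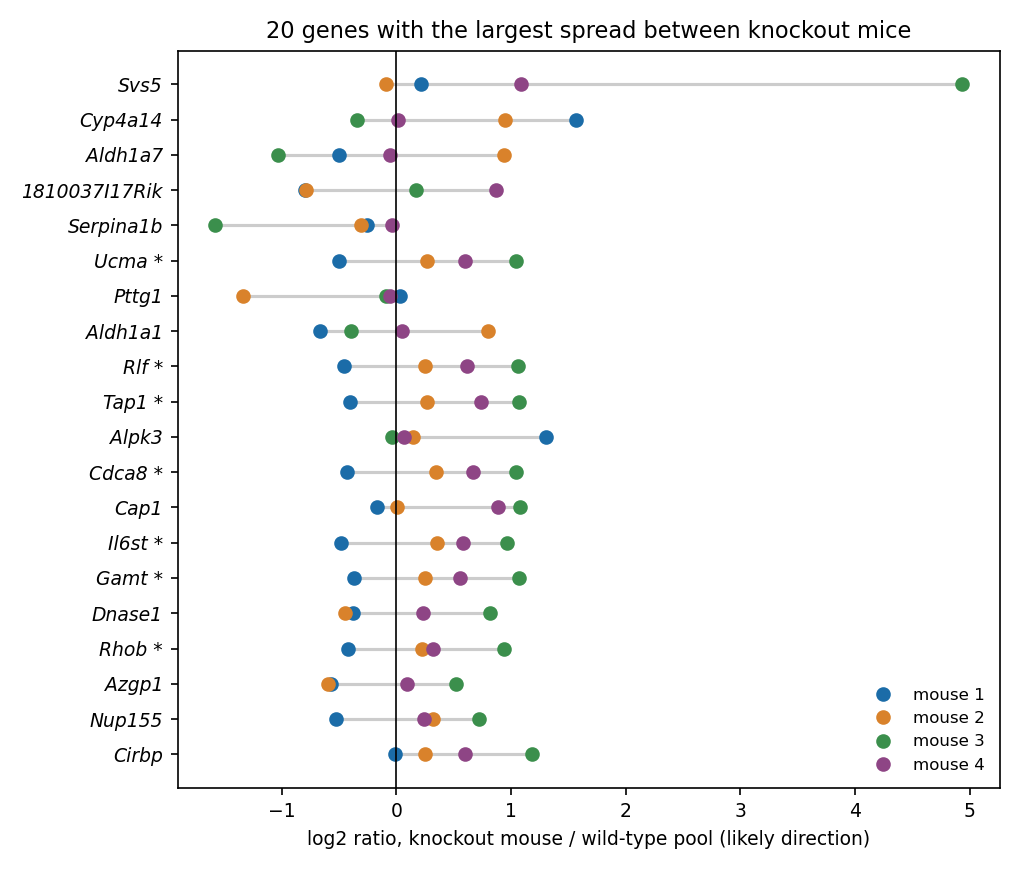
Log2 ratio of each knockout mouse over the wild-type pool (horizontal axis, likely direction) for the 20 genes with the largest standard deviation between mice among those past the F test; points are mice, grey lines join the lowest and highest mouse, and asterisks mark genes on probes that share 1 profile. Svs5 in mouse 3 stands at 4.94, apart from all other values.

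The last comparison was between the dye orientations. In limma no probe differed between the dye orientations at an adjusted p of 0.05 (smallest adjusted p 0.12), with 2040 of 10804 probes at an unadjusted p under 0.05. Among the 3966 probes with a value on every array, 139 passed.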

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

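The tests in this part were chosen after the results were seen, except the search for outlying mice and the test of segregating alleles. The wording fixed beforehand for the test of segregating alleles did not name 2 removals. These were of shared-profile genes, which were found in the data, and of pairs with alike symbols. Among 94 named genes, 7 had 1 mouse far from the other 3, where chance alone gives about 1 in 20 groups. That rate does not hold for the 20 genes picked for their spread between mice, Pttg1 and Alpk3 among them, and whether 7 exceeds chance was not tested. The gap to the nearest mouse as a share of the range was 0.916 for Pttg1 (mouse 2 at -1.34) and 0.867 for Alpk3 (mouse 1 at 1.31), both of which differed between mice. It was 0.961 for Adh1 (mouse 3 at -0.13, the others near -0.32), 0.847 for Cyp4b1 (mouse 3 at -0.07), 0.914 for Slc22a2 (mouse 1 at -0.07), 0.876 for Gstm1 (mouse 4 at 0.46) and 0.85 for Hsd11b2 (mouse 2 at -0.10, the others positive). None of Adh1, Cyp4b1, Slc22a2, Gstm1 and Hsd11b2 was past the F test between mice.

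The 252 probes that differed between mice exceeded all 99 other deals of the arrays to mice within orientation, of which the highest gave 20 probes. So 1 of 100 deals was as large and chance dealing is excluded as the source. A technical difference that runs with the mouse would also exceed the deals, so they do not separate it from a difference between animals. The 10 probes and 13 genes that differed from the wild-type pool were set against the other sign patterns of the 4 mice, none of which gave more than 0. With 8 patterns, of which 1 was as large for probes and 1 for genes, no share under 0.05 can be reached.

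A first pattern is the 26 probes that follow 1 profile over the arrays, with r above 0.9 to the central probe. Of these, 18 lie within 400 consecutive probe numbers, where 10000 random draws of 26 tested probes gave 7 at most, and 18 name no gene or several. Among the 8 genes they name, other probes with values on at least 12 arrays exist for Mark3 and Rlf. Their r with the profile was -0.58 for Mark3 and 0.18 (SE 0.28) for Rlf. The value for Mark3 argues against joint regulation of that gene, provided that its other probe measures it. The value for Rlf cannot decide, since its standard error is wide and no intensities show whether that spot was dim. Joint regulation stays open for Rlf and for the genes without another such probe. A candidate explanation is therefore that many of these spots hold the same cDNA, so that 1 transcript differing between mice is counted many times. Which transcript it would be was not tested.

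A second pattern is that Eaf2 and Slc35a5, called lower, lie 1 and 56 places from Slc15a2. Within 100 places, with Slc15a2, Eaf2 and Slc35a5 left out, 15 of 53 measured genes (28.3%) were at an unadjusted p under 0.05, against 16.7% of other genes, and 98.2% of 4928 overlapping windows of as many genes elsewhere had a lower share. Of the 15, 11 were lower and 4 higher, and none passed over all genes. Of the 11, 3 (Ndufb4, Cox17 and Rpl24) belong to the oxidative phosphorylation and ribosomal lists, and without members of these lists 12 of 50 neighbours were at that p, against 16.1% of other genes, a share above that of 92.8% of 4878 windows. Whether the neighbours hold an excess stays open, since it lies above 95% of windows only with members of these lists included. Alleles carried along with the targeted locus in a mixed C57BL/6 and 129Sv background are a candidate source. A direct effect of the targeted allele on its neighbours and an error of the single pool are others. These sources cannot be told apart here, since all 4 knockout mice carry that allele and were set against the same pool.

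A further pattern is the 161 genes that differ between mice of a mixed background, for which segregating alleles are a candidate source. Over 117 pairs of differing genes within 100 places of each other, with shared-profile genes and pairs whose symbols begin with the same 4 letters left out, the mean absolute r of the mouse profiles was 0.723, against a median of 0.73 after shuffling places (95% of shuffles between 0.676 and 0.781). Differences in alleles, in the state of the animals, in dissection and in the handling of each mouse's RNA and arrays cannot be told apart from 4 animals. No label groups the mice.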

How the results depend on the processing

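The reading of the ratio, the removal of array 3 of mouse 4, of shared-profile probes and of Slc15a2 from the lists, and the list enrichment with each mouse left out, were chosen after the data were seen. Slc15a2 was past the threshold at between -2.25 and -2.78 under all other alternatives and at 2.51 with the ratio read as channel 2 over channel 1. The 12 other called genes kept their sign in all of 220 combinations of gene and alternative, and lost the threshold in 85. These leave out the reading as channel 2 over channel 1, under which every sign turns (9 genes higher and 4 lower). From 10 probes and 13 genes changed, the counts went to 23 and 40 for probes with a value on all arrays (3966 and 2681 tested, 8 of the 13 genes still called), 2 and 2 with at least 3 mice (18450 and 9061 tested), 622 and 401 with the mouse as random block (correlation within mouse 0.053 for genes), 2 and 1 with knockout RNA in channel 2, and 6 and 4 on arrays 1 and 2. Arrays 3 and 4 gave 8 genes, and the median of arrays 18 probes. Leaving out 1 mouse gave 2 to 5 probes and 1 to 6 genes. From 5 lists past camera, the count went to 3 on arrays 3 and 4 (2 of the 5, and amino acid metabolism), 0 with an estimated correlation and 2 with fry, with or without Slc15a2. Outside the 5, the neighbours of Slc15a2 passed camera under 6 of 20 alternatives, endothelial markers under 4, amino acid metabolism under 2, and amino acid transporters and the proximal tubule, collecting duct and smooth muscle markers under 1 each. The peptide list did not pass with knockout RNA in channel 1 (adjusted p = 0.252) or on arrays 1 and 2 (0.144), nor the androgen list for probes on all arrays (0.0617). Probes differing between mice fell from 252 to 56 on arrays 1 and 2, to 53 on arrays 3 and 4, and to between 81 and 213 without 1 mouse. Dye effects rose from 0 to 2 probes at equal scale and 139 for probes on all arrays. Fewer arrays or mice lower the power and fewer tests ease the adjustment, but how far this accounts for the changes was not tested. The filter for values on all arrays also changes which probes enter. The random block, at a correlation of 0.053, took technical arrays nearly as independent animals. The cause of the other changes was not tested either. Members that did not pass changed sign for Slc22a2 (0.011) and Cry1 (-0.031) with knockout RNA in channel 1, and for Ptprc with knockout RNA in channel 2 (-0.04) and without mouse 2 (-0.033, with a range to 0.203 without other mice). List tests were not run for the random block. Tests over mice and dyes do not apply to single orientations, and no paired analysis was possible because there is 1 group. Scaling moved the median of all genes by under 0.1. Without intensities, how signal over background limits a ratio was not analysed here.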

Other observations

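The values in this part were chosen after they were seen. The Svs5 signal of mouse 3 was present on all 4 of its arrays, at 5.75, 5.49, 4.07 and 4.43, and mouse 4 stood at 1.16, 0.69, 1.86 and 0.63 on its arrays. Mice 1 and 2 had values on 2 arrays each, between -0.26 and 0.28. In mice 2, 3 and 4 the heat shock genes Hspa1a, Dnajb1, Hspa8 and Hsph1 lay below the pool and in mouse 1 above it. Hspa8 stood at 0.02, -0.14, -0.53 and -0.79 and Hsph1 at 0.11, -0.17, -0.54 and -0.50 in mice 1 to 4. Cirbp, the cold-inducible RNA-binding protein, stood at -0.01, 0.25, 1.18 and 0.60. The order of the mice is that of the shared-profile probes, and without mouse 3 Cirbp did not pass the F test (adjusted p = 0.311). Txnip, a glucose-responsive gene chosen after its values were seen, stood at 0.38 and 0.15 in mice 3 and 4 and at -0.30 and -0.62 in mice 1 and 2, opposite to Cyp4a14. Over 6191 genes, the standard deviation of the difference was smallest between mice 1 and 2 (0.161) and between mice 3 and 4 (0.171), and largest between mice 1 and 3 (0.24). The spread of single arrays also differed by mouse. Their median absolute deviation was 0.099 to 0.151 in mice 1 and 2, 0.165 to 0.233 in mouse 3 and 0.088 to 0.188 in mouse 4. Whether the differences between mice reflect the animals or the spread of their arrays was not tested.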
